A study of Escherichia coli with 6 samples.

How the data were processed

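Total RNA of Escherichia coli K-12 W3110 was measured on 6 single-channel Affymetrix arrays, 2 each for the wild type, an lsrR mutant and an lsrK mutant. The groups and replicate numbers were taken from the sample titles, which call the replicates biological. No label says whether they came from separate cultures, so the p-values measure the spread between these arrays. Per the labels' protocols, cells were grown in LB to an OD600 of 2.4, treated with an RNA protection reagent, and 6 µg of RNA per array was labelled with biotin. The free-text sample descriptions speak of embryos, at odds with the organism field, and they were not used.

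The deposited values are intensity values, 1 MAS5 signal per probe set on a linear scale, and MAS5 is named in the submitters' processing notes without a version. The 2% trimmed mean over all probe sets lay between 499.3 and 501.5 on every array, so the deposited intensity values had been scaled per array to a common level. The scaling target, any masking, detection calls and the scanner files are not given in the sources used here. The number of arrays limits the precision of every value.

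The table holds 7312 probe sets, of which 4345 name an E. coli gene, 2886 are intergenic, 59 are phage or plasmid sequences and 22 are array controls. Gene names came from the b number in the probe set name, matched to the RefSeq gene table of assembly ASM584v2 (strain MG1655), and 4183 gene probe sets matched. The other 162 kept the name on the array. That table served only for names and for which genes are neighbours, since the build behind the array is not given in the sources used here. In the platform annotation 3656 gene probe sets had 1 symbol, 589 had several and 100 had none, and names were therefore taken through the b number. A further limit is that 126 gene probe sets carry a suffix for sequence shared with other genes. A gene with several probe sets is represented by the brightest.

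Array medians over gene probe sets ranged from 243.1 to 284.2, a range of 0.23 on the log2 scale. This lay within the tolerance of 0.25 set before the data were examined, so the signals were used as deposited. Values were transformed as log2(signal + 83.9), where the pseudocount is the 20th percentile of all gene signals. Log2 fold changes are on this scale, which understates the change of genes with low signal, while folds are ratios of mean signals. Signals of phage and plasmid probe sets gave a background, with a median of 20.5 and a 95th percentile of 156.7, and 1105 gene probe sets (25.4%) lay below that percentile on all 6 arrays.

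All 6 arrays entered 1 limma fit (limma 3.58.1 in R 4.3.3) with a mean per group, 3 residual degrees of freedom and an intensity trend in the variance prior, whose median prior degrees of freedom were 3.27. The 3 contrasts were the lsrR mutant against the wild type, the lsrK mutant against the wild type, and the lsrR mutant against the lsrK mutant. Tests were two-sided, with Benjamini-Hochberg adjustment over 4345 gene probe sets and a threshold of 0.05. Unless another test is named, each gene's p-value below is from limma. On simulated arrays with 200 changed genes among 4345 per run, the lsrR to wild type contrast recovered 54.8% of changes of 1, 97.6% of changes of 2 and 100% of changes of 3 on the log2 scale over 5 runs. Of its calls there, 4.86% were false. The lsrK to wild type contrast recovered 49.1%, 93.8% and 99.1% with 5.47% false, and the contrast between the mutants 50.6%, 95.4% and 99.4% with 4.45% false. These figures hold for 200 planted changes with independent noise, while the contrasts in the data called 3, 2 and 8 genes. Adjustment over all genes is stricter when fewer genes change, so the recovery does not show that uncalled genes lack such changes. In the data lsrG in the lsrR mutant (1.99, adjusted p = 0.123) and lsrB in the lsrK mutant (-2.25, adjusted p = 0.108) did not pass.

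Shifts of 24 gene lists were tested with limma's camera (inter-gene correlation 0.01), adjusted over the lists. Of 502 list entries 14 had no probe set, 9 of them small RNAs. Genes named in the text were chosen by a rule set before the data were examined. It takes every lsr regulon member plus luxS, mtnN (listed as mtn), tqsA, flu, wza and dsrA, and up to 12 genes per direction with the largest change among those that passed with separated groups. Where fewer than 10 passed in a direction, genes with the smallest unadjusted p and separated groups fill up to 10. Of each list, 2 to 4 members with the smallest p can be named.

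The alternatives were no pseudocount, a doubled pseudocount of 167.8, leaving out the lowest 25% of gene probe sets by mean signal (3260 kept), centring on array medians, quantile normalization, fitting only the 4 arrays compared, no trend in the variance prior, the replicate number as a block, adding the intergenic probe sets, and leaving out each array in turn. When an array was left out, the remaining array of that group was assumed to vary like the other groups. Lists were also tested with an estimated correlation and with fry. A further alternative was chosen after the data were seen. It leaves out 43 gene probe sets that changed at least 2-fold and whose ratios in replicates 1 and 2 agreed within 0.02 on the log2 scale (1.4%), among signals of at least 20. A tolerance of 0.005 was looked at as well (21 of 150 gene probe sets agreed in the lsrR mutant and 10 of 122 in the lsrK mutant), and both were tried after the agreement had been noticed. Chance agreement between the 2 comparisons with the wild type was estimated from 100 simulations of unchanged groups, and, after the data were seen, with 1 wild-type array per comparison. Replicate ratios were compared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. Array controls, phage and plasmid probe sets stayed out of all tests.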

Results

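The data are MAS5 signals of 6 arrays from Escherichia coli K-12 W3110 grown in LB to an OD600 of 2.4, which the series title places in early stationary phase. There were 2 arrays each of the wild type, of an lsrR mutant and of an lsrK mutant. LsrK is the kinase that phosphorylates the quorum-sensing molecule autoinducer 2 (AI-2) inside the cell, and LsrR is the repressor of the lsr genes that phosphorylated AI-2 releases. The lsr genes encode the AI-2 importer (lsrA, lsrC, lsrD, lsrB) and enzymes that process the signal (lsrF, lsrG). The array medians over 4345 gene probe sets lay between 243.1 and 284.2. Replicates correlated across genes with r = 0.946 in the wild type, 0.965 in the lsrR mutant and 0.957 in the lsrK mutant on the log2 scale, and genes are not independent replicates. Arrays of different strains with the same replicate number correlated more highly in several cases, with r = 0.981 between the replicate 2 arrays of both mutants and 0.977 and 0.971 between the replicate 1 arrays of the wild type and the lsrR and lsrK mutants. So did wild-type replicate 1 with replicate 2 of the lsrR mutant (0.968) and of the lsrK mutant (0.97).

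The first comparison, of the lsrR mutant with the wild type, asks what loss of the repressor changes. The disrupted gene itself, lsrR (b1512), had a signal of 162 ± 9.62 (SD, n = 2) in the mutant and 1300.15 ± 94.96 (SD, n = 2) in the wild type, a log2 fold change of -2.49 ± 0.20 (SE, adjusted p = 0.0222). The signal that was left is close to the background percentile of 156.7. The importer gene lsrA (b1513) rose 6.24-fold, from 283 ± 24.3 to 1764 ± 84.7 (SD, n = 2 each, log2 fold change 2.33 ± 0.20 SE, adjusted p = 0.0222). The only other gene to pass was flu (b2000), which encodes the surface autotransporter antigen 43. Its signal fell from 1235 ± 68.7 to 127 ± 12.7 (SD, n = 2 each, log2 fold change -2.65 ± 0.20 SE, adjusted p = 0.0222), which is below the background percentile, so the size of the fall is uncertain.

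The other lsr genes had higher signals in the lsrR mutant without passing over all 4345 genes. The kinase gene lsrK was 4.09-fold higher (log2 fold change 1.95, adjusted p = 0.0576) and lsrG 4.06-fold higher (1.99, adjusted p = 0.123). The values were 3.10-fold for lsrF, 3.07-fold for lsrB, 2.97-fold for lsrD and 2.49-fold for lsrC, with adjusted p between 0.114 and 0.211. Adjusted over the list alone, 7 of the 8 lsr genes were higher and 1, lsrR, was lower, against 1 higher and 1 lower over all genes. The list rose as a whole, with a median log2 fold change of 1.58 (camera adjusted p = 5.8e-11). With an estimated correlation between genes the adjusted p was 0.585, and with fry it was 0.0235. Of the genes flanking the locus, tam, the next gene after lsrG, had a log2 fold change of 1.01 ± 0.20 and yneE one of 0.56 ± 0.16 (SE). Adjusted over the list alone, only tam was higher, and the list of 12 did not pass (adjusted p = 0.271). The AI-2 synthase gene luxS (0.24 ± 0.30 SE) and the nucleosidase gene mtn (-0.03 ± 0.26) differed by less than their errors. The AI-2 exporter gene tqsA (-0.01 ± 0.13) lay below the background percentile in all groups, so a change there could not be measured.

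**Figure D1:**
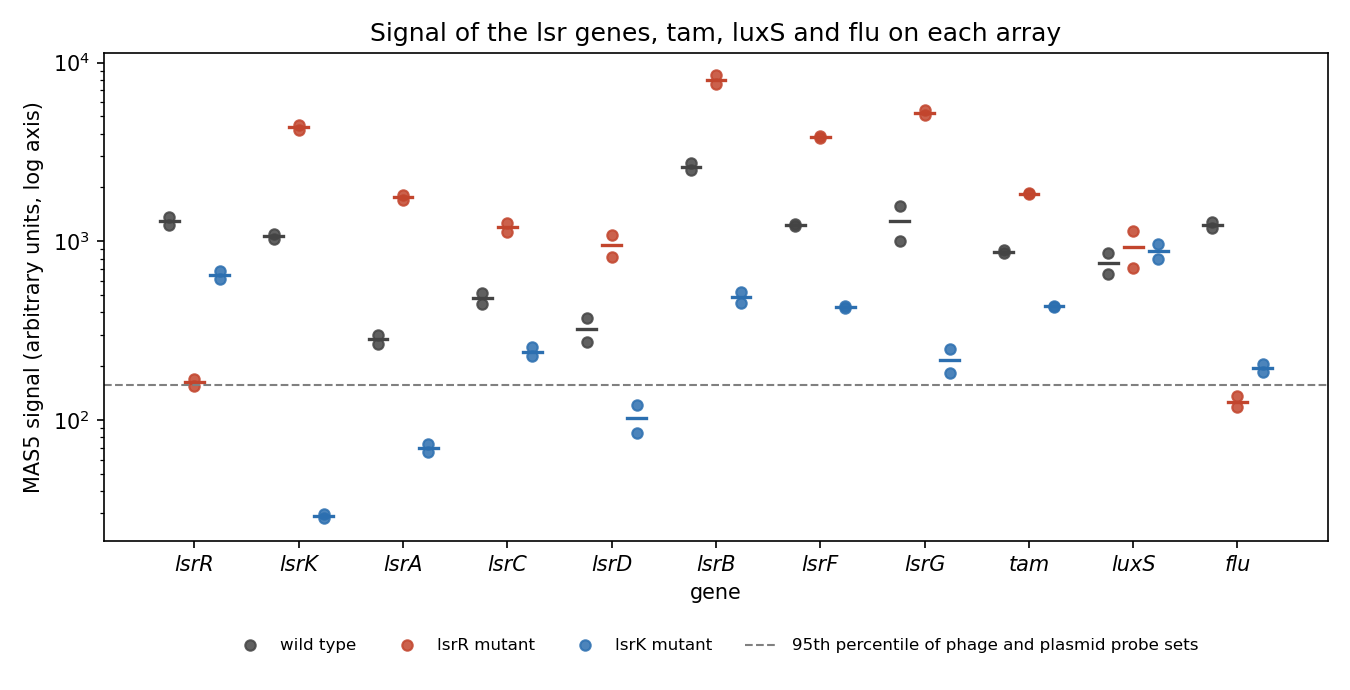
MAS5 signal (arbitrary units, log axis) of the 8 lsr genes, tam, luxS and flu on each array, with 2 points per group and a bar at the group mean; the dashed line is the 95th percentile of phage and plasmid probe sets, 156.7. For every lsr gene except lsrR the 2 lsrR mutant arrays lie above the wild type and the 2 lsrK mutant arrays below it.

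Outside the locus, no further gene passed, and the genes with the smallest unadjusted p are named next. Higher in the lsrR mutant were glnK, encoding a PII nitrogen regulator (4.28-fold, adjusted p = 0.0576), yoaG (4.79-fold, adjusted p = 0.0576), kdgT, encoding a ketodeoxygluconate transporter (3.61-fold, adjusted p = 0.114), and the colanic acid gene wcaA (3.53-fold, adjusted p = 0.114). The values for ycgX (4.598-fold) and mcbR (6.60-fold) rest on mean signals no higher than 93.8 and 47.9, below the background percentile. The wild-type signals of yoaG (44.6), wcaA (49.4) and kdgT (80.1) also lay below it, so their folds are not exact. Lower were yeeR, the neighbour of flu (5.20-fold from replicate 1 and 5.20-fold from replicate 2, adjusted p = 0.0576), and plaP, encoding a putrescine importer (log2 fold change -1.16, adjusted p = 0.123), with mutant signals of 66.2 and 119 that again lay below it. Next came ybcF (-0.71), the propionate gene prpD (-0.72), the regulator gene mhpR (-0.82), the purine gene purF (-0.77), the histidine gene hisD (-0.74) and ycdV (-0.38), with adjusted p between 0.211 and 0.406. The mutant signals of ybcF (63.6) and prpD (129) lay below the background percentile, as did both signals of ycdV, whose probe set shares sequence with other genes. In the colanic acid list 2 of 21 genes, wcaA and wza, passed when adjusted over the list alone, and neither passed over all genes. The small RNA gene dsrA had a log2 fold change of 0.41 ± 0.09 (SE, adjusted p = 0.287) at a mean signal of 44.4 in the mutant. Both wza and dsrA lay below the background percentile in all groups.

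Besides the lsr genes, 3 lists shifted in the lsrR mutant by camera. Chemotaxis and motor genes fell, with a median of -0.37 over 13 genes and 12 of them lower (adjusted p = 0.000142, but 0.585 with an estimated correlation). Among these the methyltransferase gene cheR had -0.80 ± 0.36, the receptor gene tap -0.81 ± 0.37 and the motor gene motB -0.60 ± 0.30 (SE). The SOS response list of DNA damage genes fell, with a median of -0.25 over 20 genes (adjusted p = 0.00643, but 0.843 with an estimated correlation), with sbmC at -0.66 ± 0.45 and ruvA at -0.31 ± 0.22. Acid resistance genes rose, with a median of 0.22 over 15 genes (adjusted p = 0.00903, but 0.585 with an estimated correlation), with gadE at 0.22 ± 0.07 and hdeA at 0.63 ± 0.25, but the median signal of that list was only 45.0. No member of these 3 lists passed on its own, also not when adjusted over the list alone. With fry the adjusted p was 0.273 for chemotaxis, 0.966 for SOS and 0.273 for acid resistance. The SOS call was also lost without wild-type replicate 2 (adjusted p = 0.97) or lsrR mutant replicate 1 (0.359), and the acid resistance call without wild-type replicate 2 (0.0728), without lsrR mutant replicate 2 (0.141), with quantile normalization (0.413) or without the lowest signals (0.0699). The other lists did not pass, with flagella nearest (median -0.17, adjusted p = 0.0724). Iron uptake passed as higher in 3 of 12 alternatives, such as without the lowest signals (0.0251), and as lower in 1, without wild-type replicate 2 (0.0138). Adjusted p was 0.133 for colanic acid, 0.225 for the TCA cycle and 0.271 for iron uptake, AI-2 synthesis and RpoS-dependent genes. It was 0.393 for anaerobic respiration, 0.508 for small RNAs, 0.520 for envelope and phage shock, 0.589 for other biofilm genes and the phosphate regulon, and 0.620 for tryptophan and indole. It was 0.621 for curli and the methionine regulon, 0.883 for ribosomal proteins, 0.924 for CRP-dependent genes, 0.928 for type 1 fimbriae and for ribose transport, and 0.970 for heat shock. The median was above 0 while the test leaned lower for ribosomal proteins (median 0.04), CRP-dependent genes (0.02), curli (0.05), the methionine regulon (0.04), RpoS-dependent genes (0.01) and other biofilm genes (0.01).

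In all, 3 of 4345 genes passed in limma, 1 higher and 2 lower. At an unadjusted p under 0.05 there were 208 genes, 161 higher and 47 lower, where 217 would be expected by chance. The arrays of both groups were separated for 28.7% of genes, and chance gives 33.3%. Both chance values assume independent arrays, but deviations of arrays with the same replicate number correlated at 0.451 in these 2 groups. The counts therefore do not show that no further gene changed. None of the 3 passed with the replicate number as a block (adjusted p = 0.0564 for flu and lsrR, 0.0606 for lsrA). The block left their estimates unchanged with smaller errors (SE 0.172 for flu, 0.175 for lsrR and 0.181 for lsrA), but used up a residual degree of freedom. Their calls were also lost with 1 array left out, even an lsrK mutant array outside this comparison, where fewer residual degrees of freedom remained. Such losses do not show dependence on a single array, and the direction was the same each time. Mutant to wild type ratios also agreed closely between replicates at many changed genes. Only probe sets with signals of at least 20 on all arrays compared were counted, which leaves out wza, dsrA and mcbR. At 8 of the 19 other named genes that changed at least 2-fold the ratios were within 1.4% of each other. The naming rule favours close replicates, and over all changed gene probe sets counted in this way the share was 32 of 150 (21.3%). Examples are lsrF (3.10 and 3.10), plaP (3.10 and 3.10), yeeR (5.20 and 5.20), kdgT (3.61 and 3.60) and yoaG (4.79 and 4.80). The median difference of the 2 ratios was 0.393 on the log2 scale among 3263 gene probe sets that changed by less than 0.5.

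The second comparison, of the lsrK mutant with the wild type, asks what follows when AI-2 cannot be phosphorylated by this kinase. The disrupted gene lsrK (b1511) had a signal of 29.0 ± 1.27 in the mutant and 1064 ± 55.9 in the wild type (SD, n = 2 each), a log2 fold change of -3.35 ± 0.20 (SE, adjusted p = 0.00953). Every other lsr gene was lower in the mutant. The binding protein gene lsrB (b1516) went from 2618 ± 178 to 486 ± 46.3 (SD, n = 2 each, log2 fold change -2.25 ± 0.25 SE, adjusted p = 0.108). The values were -2.17 for lsrG, -1.37 for lsrF, -1.26 for lsrA, -1.12 for lsrD, -0.92 for lsrR and -0.79 for lsrC, with adjusted p between 0.15 and 0.439, and the mutant signals of lsrK, lsrA (69.4) and lsrD (103) lay below the background percentile. The gene flu fell from 1235 ± 68.7 to 195 ± 14.1 (SD, n = 2 each, log2 fold change -2.24 ± 0.20 SE, adjusted p = 0.0417).

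Adjusted over the list alone, 8 of 8 lsr genes were lower, against 1, lsrK, over all genes. The list includes lsrK, the disrupted gene. The list fell with a median of -1.31 (camera adjusted p = 5.28e-22), and the adjusted p was 0.322 with an estimated correlation and 0.00767 with fry. In the flanking list tam had a log2 fold change of -0.89 ± 0.20 (SE) and did not pass, and the list did not pass (adjusted p = 0.855, median 0.06 while the test leaned lower). The values for luxS (0.20 ± 0.30 SE) and mtn (-0.09 ± 0.26) were within their errors, and tqsA (-0.22 ± 0.13), below the background percentile, had an adjusted p of 0.999.

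No gene was higher in the lsrK mutant at the threshold. Those with the smallest p were glnK (3.60-fold, adjusted p = 0.15), the cold shock family gene cspF (3.89-fold, adjusted p = 0.159, from a wild-type signal of 121 below the background percentile), cnu, encoding a nucleoid protein (3.74-fold, adjusted p = 0.182), and dctR (5.20-fold, adjusted p = 0.15). The cnu and dctR signals lay below the background percentile, as did those of ycgX, dsrA, yhaB, yhiL, wza and nrfF, which were 2.83-fold to 4.39-fold higher with adjusted p between 0.212 and 0.244. Lower without passing, besides lsr genes, were yeeR (-1.23, adjusted p = 0.15), ycdV (-0.58), ybcF (-0.74) and the histidine gene hisC (-1.43), the last 3 with adjusted p between 0.226 and 0.26. The mutant signals of yeeR (98.8), ybcF (61.2) and ycdV (22.2, with a shared probe set) lay below the background percentile.

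RpoS-dependent stationary phase genes fell as a list, with a median of -0.15 over 31 genes and 25 of them lower (camera adjusted p = 0.00221, but 0.322 with an estimated correlation), and no member passed. The trehalose synthesis gene otsA had -0.37 ± 0.11, the catalase gene katE -0.63 ± 0.20 and aldB -0.54 ± 0.23 (SE). Acid resistance genes rose, with a median of 0.14 over 15 genes (adjusted p = 0.00947, but 0.426 with an estimated correlation), led by the regulator gene gadE at 0.37 ± 0.07, the 1 member to pass when adjusted over the list alone, and the arginine decarboxylase gene adiA at 0.47 ± 0.13. With fry the adjusted p was 0.214 for the RpoS list and 0.404 for acid resistance. The acid resistance call was lost without wild-type replicate 2 (0.121), without the lowest signals (0.421) and with quantile normalization (0.132). Ribosomal protein genes were higher in 48 of 54 cases with a median of 0.23, and chemotaxis genes lower in 12 of 13 with a median of -0.26, without passing (adjusted p = 0.0602 for both). Among 12 alternatives chemotaxis passed in 3, and ribosomal proteins passed as higher in 5, such as without the lowest signals (0.00422), and as lower in 2, without wild-type replicate 2 (0.026) or lsrK mutant replicate 1 (0.0206). Adjusted p was 0.1002 for the methionine regulon and the TCA cycle, 0.187 for anaerobic respiration, 0.339 for ribose transport, 0.362 for envelope and phage shock and 0.463 for SOS. Flagella, curli and heat shock had 0.465, AI-2 synthesis and tryptophan 0.511, type 1 fimbriae 0.651, iron uptake 0.656 and other biofilm genes 0.722. Colanic acid had 0.855, the phosphate regulon 0.895, CRP-dependent genes 0.989 and small RNAs 0.992.

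**Figure D2:**
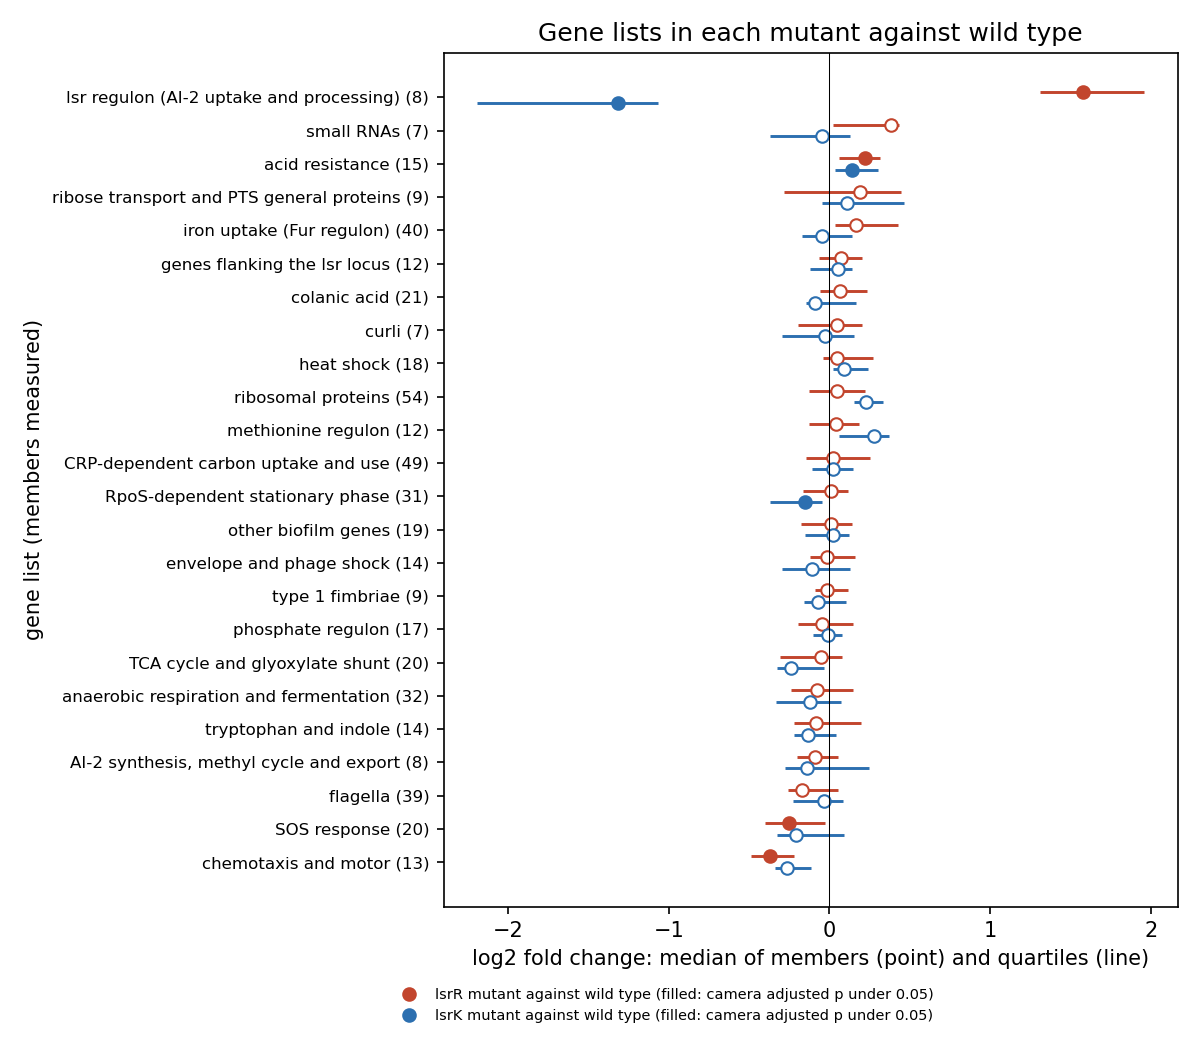
Median log2 fold change of each gene list (points) with its quartiles (lines) in the lsrR mutant (red) and the lsrK mutant (blue) against the wild type; filled points passed camera at an adjusted p under 0.05. The lsr regulon stands apart in opposite directions, at 1.58 and -1.31, and the other medians lie between -0.37 and 0.38.

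In this comparison 2 of 4345 genes passed in limma, both lower, and 190 had an unadjusted p under 0.05. Only lsrK passed with the replicate block (flu adjusted p = 0.0675). Both calls were lost with 1 array left out, where fewer residual degrees of freedom remained, even for an lsrR mutant array outside this comparison. Both genes stayed lower each time. Among named genes that changed at least 2-fold, 18 had signals of at least 20 on all arrays compared, which leaves out dctR, dsrA, yhiL and wza. Ratios agreed within 1.4% between replicates at 6 of the 18, among them lsrF (2.90 and 2.90 lower), ybcF (2.58 and 2.59 lower) and glnK (3.60 and 3.60 higher).

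The third comparison sets both mutants against each other and so tests whether their effects differ. The kinase gene lsrK, which is disrupted in the lsrK mutant, differed by 5.29 ± 0.20 (SE) on the log2 scale (4348 against 29.0, adjusted p = 0.000558). Its difference was thus partly built into the strains. The importer and processing genes were all higher in the lsrR mutant, lsrG by 4.16 ± 0.29, lsrB by 3.83 ± 0.25, lsrA by 3.59 ± 0.20, lsrF by 2.94 ± 0.22, lsrD by 2.47 ± 0.25 and lsrC by 1.98 ± 0.21 (SE, adjusted p between 0.0024 and 0.0362). In the lsrK mutant lsrK, lsrA and lsrD lay below the background percentile, so these sizes depend on the pseudocount and give no order. Across the alternatives lsrK ranged from 4.52 to 7.23, lsrA from 3.03 to 4.67 and lsrD from 2.05 to 3.22, and by ratio of mean signals lsrA (25.4) was above lsrG (24.3) and lsrB (16.5). The gene tam (b1519) was the eighth to pass, at 1839 ± 15.8 against 432 ± 3.25 (SD, n = 2 each, log2 difference 1.90 ± 0.20 SE, adjusted p = 0.0374), and yneE, next to it, differed by 0.87 ± 0.16 (SE) and passed over the list of flanking genes alone. The repressor gene lsrR was at 162 in its own mutant and 648 in the lsrK mutant (log2 difference -1.57, adjusted p = 0.0952).

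All 8 genes that passed were higher in the lsrR mutant. Adjusted over the list alone, 7 lsr genes were higher and 1 lower, and the list had a median difference of 3.27 (camera adjusted p = 1.15e-22, 0.488 with an estimated correlation, 0.00161 with fry). The list includes both disrupted genes. For flu the mutants differed by -0.41 ± 0.20, for wza by -0.03 ± 0.10 and for dsrA by -0.11 ± 0.09 (SE, adjusted p = 0.999 each), and luxS, mtn and tqsA also had an adjusted p of 0.999. Genes with the next smallest p were ompW, an outer membrane protein gene (2.92-fold higher in the lsrR mutant, adjusted p = 0.131), and argW (6.53-fold, adjusted p = 0.131, below the background percentile). Lower in the lsrR mutant without passing were yiiX (-1.27), yidW (-1.56), ynaE (-2.24), dgcQ (-1.17) and fsaB (-1.69), with adjusted p between 0.111 and 0.224. The lsrR mutant signals of yiiX (83.3), dgcQ (124) and fsaB (66.1) lay below the background percentile, and the probe set of ynaE shares sequence with other genes. The signals of sieB, yncH, appY and yadS, also lower there, lay below the background percentile.

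The methionine regulon was lower in the lsrR mutant than in the lsrK mutant, with a median of -0.20 over 12 genes (camera adjusted p = 0.0302), with the methionine synthase gene metE at -1.08 ± 0.26 (SE), which did not pass over this list alone (0.0644) and passed over the AI-2 synthesis list that also holds it (0.0429). Ribosomal protein genes were lower too, with a median of -0.21 over 54 genes (adjusted p = 0.0302). With an estimated correlation the adjusted p was 0.937 for both, with fry it was 0.998 for both, and with quantile normalization it was 0.0703 for the methionine regulon and 0.057 for ribosomal proteins. Without lsrR mutant replicate 2 it was 0.314 for the methionine regulon and 0.182 for ribosomal proteins; without lsrK mutant replicate 1 it was 0.905 for the methionine regulon, and ribosomal proteins passed in the opposite direction (0.0421). The other 21 lists did not pass, with iron uptake, SOS, colanic acid and RpoS-dependent genes nearest (adjusted p = 0.102 each). Iron uptake passed as higher in 6 of 12 alternatives, some of which leave 1 array in a group. The called methionine and ribosomal lists passed as lower in 7 each, and ribosomal proteins as higher in 1. The adjusted p was 0.455 for the genes flanking the locus, whose median was -0.03 while the test leaned higher, and 0.808 for the AI-2 synthesis list.

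Of the 8 genes, 6 passed with the replicate block, without tam (adjusted p = 0.0569) and lsrC (0.0508). Fewer passed with any 1 array left out, also a wild-type array outside this comparison, where fewer residual degrees of freedom remained. All 8 stayed higher in the lsrR mutant each time. At 3 of the 8, lsrK, lsrC and lsrF, the ratios of replicates 1 and 2 agreed within 1.4%. Over all changed gene probe sets of this comparison with signals of at least 20, 7 of 80 agreed, which lay within the draws of unchanged ones (at most 12).

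**Figure D3:**
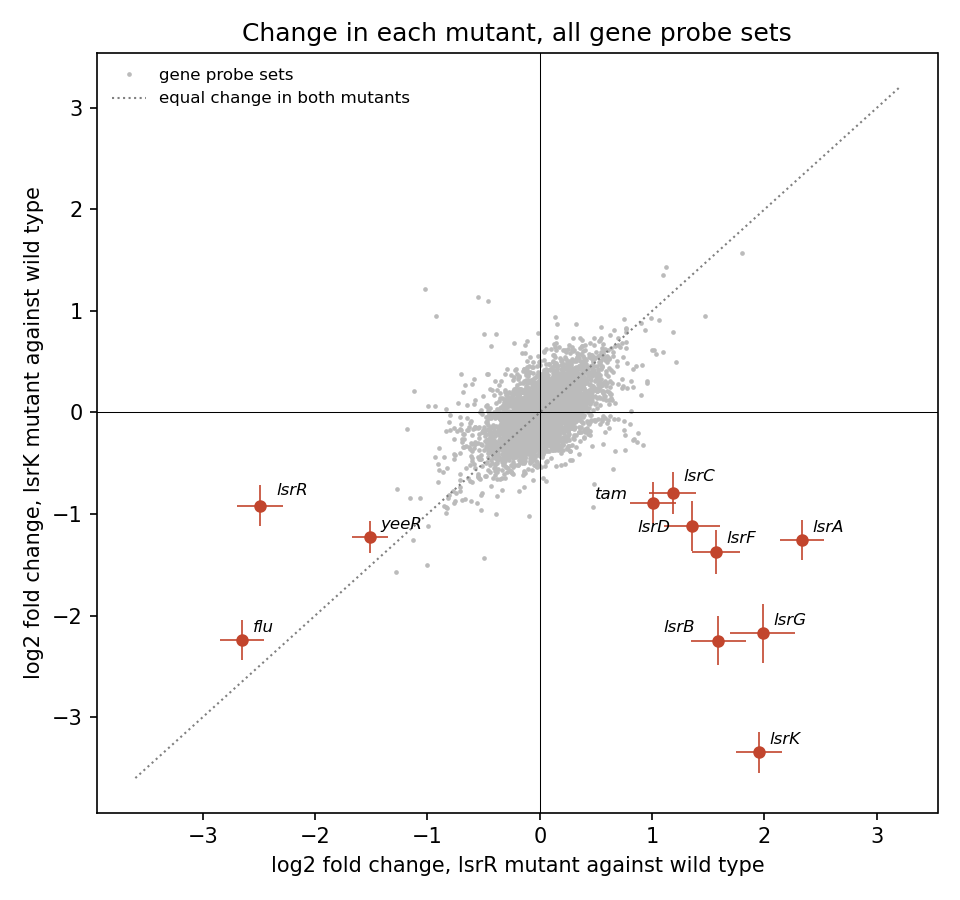
Log2 fold change of every gene probe set in the lsrR mutant (horizontal axis) and the lsrK mutant (vertical axis) against the wild type, with bars of 1 SE in each direction for named genes; the dotted line marks equal change. The lsr genes other than lsrR, and tam, lie at lower right, while flu, at -2.65 and -2.24, and yeeR lie near the line.

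Both mutants were compared with the same wild-type arrays, so their changes share chance values. Across all genes the changes correlated with r = 0.462, and simulated unchanged groups gave 0.503. The covariance was 0.0371 against 0.0452 in the simulations. At an unadjusted p under 0.05, 59 genes were higher in both mutants, against a mean of 26.5 and at most 42 in the simulations and 4.9 for independent lists. Some of them had closely agreeing replicate ratios, such as glnK in the lsrK mutant and ycgX in the lsrR mutant. How many of the 59 did was not counted, so this excess does not show a shared response. Lower in both were 19 genes, 1 of them an lsr gene, against 25.9 in the simulations and 0.6 for independent lists. Opposite changes were seen at 14 genes, 7 of them lsr genes, against 1.3 in the simulations and 3.6 for independent lists. The 7 include lsrK, which is disrupted in the lsrK mutant. With 1 wild-type array per comparison, so that none was shared, the changes correlated with r = -0.242 or -0.264 depending on the assignment. The comparisons then used wild-type arrays of different replicate number, so a shift by number would enter them with opposite sign and lower r. This split therefore cannot show whether the agreement across all genes came from the shared controls alone. The gene flu stayed lower in both mutants (-2.59 and -2.29, or -2.70 and -2.19). The simulated arrays were independent of the replicate number, so they leave out any pairing of arrays by number.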

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

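The tests of replicate ratios and of flu were chosen after the values had been seen, while the contrast between the mutants was planned. The first test of shared arrays for flu, a count of genes lower in both mutants (19, against at most 40 in simulations), was replaced because it did not concern flu, and both left chance open. A first gene against intergenic test, which counted a probe set once per comparison and was not matched on signal, was likewise replaced, with the same outcome.

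The effects of the mutations differed at 8 genes by the test of the difference itself, the lsrR effect minus the lsrK effect on the log2 scale. The differences were 5.29 for lsrK, 4.16 for lsrG, 3.83 for lsrB, 3.59 for lsrA, 2.94 for lsrF, 2.47 for lsrD, 1.98 for lsrC and 1.90 for tam. At lsrK, the gene disrupted in the lsrK mutant, a difference was built into the strains, so its size does not measure regulation. In the lsrK mutant lsrK (29.0), lsrA (69.4) and lsrD (103) lay below the background percentile of 156.7, so the sizes depend on the pseudocount and give no order. The wild type lay between the mutants at each of them, as the plot of signal by gene shows for these genes.

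Signal also appeared in probe sets outside the comparisons. The spike-in control probe sets for the Bacillus genes dap, lys, phe and thr gave signal on wild-type replicate 2, up to 10147 and at least 764 over 12 probe sets, while no other array went above 170.1. Intergenic probe set 996 had a mean of 15208.8 in the lsrR mutant, 1851 in the wild type and 768 in the lsrK mutant. Intergenic probe set 997 had 588.0 in the lsrR mutant, 66.0 in the wild type and 26.5 in the lsrK mutant. Intergenic probe set 1335 had 13.2 in the lsrR mutant and 55.1 in the lsrK mutant against 298 in the wild type, like flu. By their names, 996 spans positions 1598234 to 1598311 and 997 spans 1599266 to 1606131 on the same strand, so they lie close together. The genome build is not given, so these probe sets were not placed relative to genes. Whether they repeat the changes of nearby genes is open. When intergenic probe sets were tested with the genes, all 3 passed in the lsrR mutant, only 1335 in the lsrK mutant, and 996 and 997 between the mutants, where tam lost its call.

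The next counts compare the mutant to wild type ratios of replicates 1 and 2. They cover gene probe sets that changed at least 2-fold, with signals of at least 20 on all arrays compared. Of these, 32 of 150 in the lsrR mutant and 19 of 122 in the lsrK mutant had ratios agreeing within 1.4%. In 10000 draws of unchanged gene probe sets matched on signal, at most 11 and 8 did so. Noise like that of unchanged genes therefore does not account for this agreement. With the replicate numbers crossed 11 and 14 agreed. No draws were made for crossed ratios, and whether these are the same probe sets was not checked, so dependence on the numbering is open. Between the mutants the count was within the draws (7, against at most 12). A shift shared by arrays of 1 replicate number would also act on intergenic probe sets. Over both comparisons, each probe set counted once, 2 of 73 changed intergenic ones agreed against 38 of 215 genes. Of 10000 draws of changed genes of like signal, 0 held as few (a share of 0.0001 with the observed set counted). The draws were matched on signal alone, not on noise or on the share of true changes, so they do not exclude such a shift as a contributor. Of the 38 agreeing ratios 30 lay within 0.01 of a multiple of 0.1, such as 2.30 and 3.10, against 44 of 177 other ratios (one-sided Fisher's exact p = 6.4e-10, where 20% would be chance), a pattern consistent with values on 1 array having been set from those on another by a 1-decimal fold. The sources used here do not say how the table was made, the scanner files that could settle it were not analysed here, no biological explanation was tested, and whether the arrays are independent measurements at these genes is open.

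The gene flu fell in both mutants, and its neighbour yeeR had lower values without passing. A single deviating wild-type array does not account for this, since flu stayed at -2.19 or lower on the log2 scale in either mutant without either wild-type array. Chance from the shared arrays is not excluded by a broad measure. In 2 of 100 simulations of unchanged groups some gene fell as far in both comparisons, the strongest at -2.50. That counts the noisiest of 4345 genes and leaves out any pairing by replicate number. With 1 wild-type array for each mutant and none shared, flu stayed at -2.59 and -2.29, or -2.70 and -2.19. These are the same falls as with a wild-type array left out, so they add no separate check. A difference between strain stocks, such as the on and off states through which flu is known to switch, may also lower it in both mutants; the difference between the mutants at flu did not pass (adjusted p = 0.999), which this explanation allows but so would an effect of either mutation. With 1 wild-type strain these cannot be told apart.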

How the results depend on the processing

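The alternative without agreeing replicate ratios was chosen after the data were seen; the others were planned. In the lsrR mutant the 3 calls became 6 without the lowest signals, 5 with quantile normalization, 6 with no trend, 6 with intergenic probe sets, 2 without agreeing ratios (lsrR itself left out), 0 with only 4 arrays and 0 with the replicate block. In the lsrK mutant the 2 calls became 3 with no trend, 3 with intergenic probe sets, 1 with no pseudocount, 1 with only 4 arrays, 1 with the replicate block and 0 without agreeing ratios (lsrK itself was left out, and flu was tested and lost its call). Between the mutants the 8 calls became 9 with no trend, 9 with intergenic probe sets (996 and 997 gained, tam lost), 5 with only 4 arrays and 4 without agreeing ratios (lsrK, lsrC and lsrF were left out, and tam was tested and lost its call). Leaving out 1 array gave fewer calls in each comparison, but with fewer residual degrees of freedom, so the losses alone do not show dependence on a single array. The direction of each called gene held throughout. Deviations of arrays with the same replicate number correlated at 0.451 (wild type and lsrR mutant), 0.257 (wild type and lsrK mutant) and 0.556 (both mutants), all above 0. These arrays thus shared deviations by number, which the main fit leaves out. Only 2 numbers exist and no label says what they share, so whether the arrays were paired, and by what, is open. The block left 0 of 3 calls in the lsrR mutant, 1 of 2 in the lsrK mutant and 6 of 8 between the mutants. Of list calls, 0 held with an estimated correlation in each comparison and 1 with fry in each. In the lsrK mutant the 3 lists became 5 without the lowest signals and 6 with the replicate block, and between the mutants 3 became 1 with quantile normalization. Leaving out 1 array gave 4 to 8, 3 to 9 and 3 to 6 lists. Uncalled values changed sign: between the mutants luxS was -0.023 and mtn -0.005 (from 0.04 and 0.05) when centred, and in the lsrR mutant mtn was 0.003 (from -0.03) with quantile normalization. Leaving out 1 array, luxS ranged from -0.28 to 0.356 between the mutants and from -0.078 to 0.559 in the lsrR mutant; mtn from -0.318 to 0.148 in the lsrK mutant, from -0.181 to 0.285 between the mutants and from -0.207 to 0.142 in the lsrR mutant; tqsA from -0.114 to 0.092 in the lsrR mutant; and wza from -0.073 to 0.006 between the mutants. Counted once per gene and setting, calls were lost 17 times and gained 10 times under settings other than leaving out 1 array. These counts restate the changes in calls given above and are not further genes. Where not stated otherwise, the cause was not tested. Signals below 156.7 lie within the range of the phage and plasmid probe sets, whose median was 20.5. Single genes were not tested against background, so whether such signals exceed it is open.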

Other observations

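The tests of acid resistance genes were chosen after the shift had been seen, and the rule was amended after its value was known, to require at least 3 members above background, which turned its outcome from excluded to undecided. As a list these genes shifted higher in both mutants by camera only, since with an estimated correlation the adjusted p was 0.585 and 0.426, and with fry 0.273 and 0.404, and no member passed over all genes. Signals near background are a candidate explanation, as only 1 of the 15 members had a mean signal above the background percentile of 156.7. Its log2 fold change was 0.63 in the lsrR mutant and 0.25 in the lsrK mutant, while the medians of the other 14 were 0.18 and 0.13. Both comparisons also share wild-type replicate 2, the array with spike-in signal, without which neither call held (adjusted p = 0.0728 and 0.121) and the smaller median against replicate 1 alone was 0.05. A single gene above background is too few to decide, so background, that array and a change in these genes cannot be told apart.

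The brightest signal on an array followed the replicate number. It was 47880, 54510 and 48646 on the replicate 1 arrays of the wild type, lsrR mutant and lsrK mutant, and 26701, 32097 and 30443 on the replicate 2 arrays.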
